A study of Mus musculus with 2 samples.

How the data were processed

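The data are total RNA-seq libraries of left cerebral cortex from 2 male B6CASTF1/J mice, 25 days old. The labels give them as biological replicates 1 and 2 of 1 group, with tissue numbered 03 and 04 in a biobank, 300 ng of RNA each, and a spike-in mix meant for stranded libraries with ribosomal RNA reduced. Replicate numbers come from the labels. Both samples carry the same donor entry there, so that they are separate animals is an assumption from the biobank numbers and the words biological replicate, and every SD over 2 animals rests on it.

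Each library had a gene table and a pair of transcript tables, on mm10 with GENCODE M21 annotation, per the file list deposited with each library. The gene table and the first transcript table hold expected counts, which need not be whole, and TPM; per the file headers they also hold posterior mean estimates of TPM, and their column names are those that RSEM writes. The second transcript table holds estimated counts and TPM under column names that kallisto writes, per the file headers. The programs' versions and the read aligner are not given in the sources used here. In the deposited TPM columns the values of all rows of a file, spike-ins and mitochondrial genes included, sum to the same total, so abundant short RNAs lower the TPM of every other gene. In the gene table effective length is the length less 99 bases, and 2398 short genes have an effective length of 0. In the second file long transcripts were shortened by 345.16 bases in replicate 1 and 340.16 in replicate 2. The second file lacked 95 transcripts, all on unplaced scaffolds.

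The gene table held 55536 annotated genes, 96 ERCC spike-ins, 1 phiX row and 26248 numbered rows that name no gene. Total expected counts were 30503944 in replicate 1 and 33263801 in replicate 2. The numbered rows, with 7 and 10 counts, or 2.3e-05% and 3.0e-05% of the counts, were left out of library sizes. For a gene with a 2 kb transcript, 3 counts, the limit that a count of 0 allows, correspond to 0.078 and 0.070 TPM. Counting intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. Bootstrap intervals of list medians resample the genes of a list, and Wilson intervals take the genes of a set as units. Neither kind covers the spread between animals, and genes of 1 list are not independent.

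The labels give 1 group, so no test between groups was possible, and the animals were compared as 1 against 1 without p-values. Levels are the mean and SD of TPM over 2 animals, and a gene counted as detected at 1 TPM or more in both. Differences are log2 of replicate 2 over replicate 1 on TPM + 0.5, which understates changes of low genes; a gene's counting interval is the exact binomial 95% interval of its TMM-scaled counts. TPM differences also carry differences in estimated transcript length. For each of 36 gene lists, with 383 entries, the median log2 difference of members with a mean expected count of at least 10 was placed among 10000 random lists of the same size, drawn for each member from the 200 genes nearest in mean TPM; 35 lists had at least 3 such members. The count minimum for list members and the number of nearest genes were chosen after the files were read, because members with few counts add noise, and all members with any count were tried as an alternative. Expected counts were rounded to whole numbers for edgeR (common dispersion after its expression filter, TMM) and DESeq2 (size factors and median dispersion). Gene sums of the second file, isoform shares, gene pair ratios and spike-ins were computed from the deposited TPM and counts. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

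The steps were tested on counts simulated for 55536 genes from the real means and library sizes. With a biological coefficient of variation of 6% and no changed gene, edgeR returned 5.94% over 17673 genes. With 200 genes changed it returned 11.0%, because in 1 group each gene that differs between the libraries adds to the dispersion, so the value for the animals is an upper figure for the spread of unchanged genes. The DESeq2 median returned 10.2% for the same 6% with no changed gene, so it did not recover the simulated spread and is given as an alternative only. Among genes with a mean count of at least 100, 100 of 100 changed 4-fold were over 2-fold apart, the median log2 of 100 changed 2-fold was 0.98, and 0 of 12394 unchanged ones were over 2-fold apart; genes with fewer counts were not part of this. A list of 12 genes shifted by 0.4 was recovered at 0.41, at percentile 100, and 4 of 100 unshifted lists fell outside the central 95% over 18171 genes.

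The gene lists, pairs and isoform genes, the quantities compared and the rule for naming genes were fixed before the data were examined; which summary stands for each group of lists was chosen afterwards. The report names, of each list, up to 4 members with the highest and 2 with the lowest mean TPM; all genes of the sex check, the 20 pairs and the 40 isoform genes; the 10 highest genes overall and among nuclear-encoded genes; the 10 largest differences in each direction between animals among genes with a mean expected count of at least 100; the 10 largest log2 ratios in each direction between the files among genes at 5 TPM or more in either file, in both animals; and, in a list beyond percentiles 2.5 or 97.5, the 4 members with the largest difference. The single-gene levels, pair ratios and isoform shares of some of these genes are not reported here, also among the alternatives, while the genes still count in lists and totals. Ctgf of the lists is Ccn2 in the annotation, and for the symbols Dlx6os1 and Rmrp, which name more than 1 gene, the longest was used. Genes that share reads with near-identical copies, such as haemoglobins, mitochondrial-like pseudogenes and Snurf, are given as uncertain.

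Alternatives were TPM rescaled to nuclear-encoded genes, the second file, posterior mean estimates, other detection levels, pseudocounts, filters and scalings, unmatched random lists, all list members with any count, library-scaled counts with no pseudocount, and each replicate left out. Allele-specific expression was not analysed here, and deposited files listing each library's contents held no measurement and were not used here.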

Results

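Total RNA was measured in the left cerebral cortex of male B6CASTF1/J mice, a first-generation cross of the C57BL/6J and CAST/EiJ strains, at 25 days of age. There was 1 group of 2 animals, called replicate 1 and replicate 2, and 300 ng of RNA entered each library. The gene table held 30503944 expected counts for replicate 1 and 33263801 for replicate 2. Of 55536 annotated genes, 15454 reached 1 TPM in replicate 1, 15202 in replicate 2 and 14744 in both. With 1 group the design implied no contrast between conditions, so the values below are levels, given as mean ± SD over the 2 animals (n = 2), and the difference between the animals. No test was run between them, and a statement that a gene was higher or lower compares these 2 libraries only. Coordinates are on mm10.

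Neuronal genes were the most abundant of the cell type markers. All 10 pan-neuronal genes were detected at 1 TPM or more in both animals, with a median of 336.15 ± 4.55 TPM (SD, n = 2). Snap25, a component of the synaptic vesicle fusion machinery (ENSMUSG00000027273.13, chromosome 2, 136713453 to 136782428), stood at 1161.6 ± 9.08 TPM. Syt1, the calcium sensor of fast transmitter release, stood at 527.42 ± 17.1 TPM, Map2 at 460.25 ± 18.0 TPM and Eno2 at 439.31 ± 4.19 TPM. The lowest of the list were Nefl at 150.43 ± 0.45 TPM and Rbfox3 at 146.55 ± 4.66 TPM.

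The listed genes of glutamatergic neurons had a far higher median than those of GABAergic neurons, which depends on the genes listed, and the 2 lists overlapped. The 10 glutamatergic genes had a median of 202.61 ± 1.25 TPM and the 10 GABAergic genes one of 14.86 ± 0.15 TPM. Camk2a (ENSMUSG00000024617.16, chromosome 18, 60925618 to 60988152), a kinase of excitatory synapses, stood at 1205.6 ± 82.4 TPM, Nrgn at 1041 ± 5.40 TPM, the vesicular glutamate transporter gene Slc17a7 at 669.55 ± 8.02 TPM and Arpp21 at 354.94 ± 4.71 TPM. The transcription factor genes Neurod6 and Emx1 were the lowest, at 28.73 ± 1.78 and 14.63 ± 0.08 TPM. Among GABAergic genes, Gad1, which makes a GABA-synthesising enzyme, stood at 136.72 ± 0.03 TPM, Gad2 at 41.68 ± 0.43 TPM and Slc32a1 at 35.16 ± 0.83 TPM. Dlx1 stood at 7.57 ± 1.58 TPM and Dlx5 at 2.87 ± 0.06 TPM.

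Of 15 interneuron subclass genes, 13 were detected. The neuropeptide genes Sst and Npy stood at 189.27 ± 2.64 and 102.6 ± 2.16 TPM, Lamp5 at 125.28 ± 8.69 TPM and the calcium-binding protein gene Pvalb at 41.47 ± 0.08 TPM. Th at 0.65 ± 0.33 TPM and Chodl at 0.44 ± 0.13 TPM lay under the detection level, on between 14 and 26 counts per library.

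Layer markers were all detected, 10 of 10 for upper and 14 of 14 for deep layers. The upper-layer list had a median of 24.15 ± 2.68 TPM, led by Cux2 at 100.86 ± 16.0 TPM, Rasgrf2 at 96.85 ± 18.1 TPM, Calb1 at 72.71 ± 3.32 TPM and Cux1 at 49.63 ± 5.03 TPM, with Rspo1 at 5.62 ± 0.12 TPM and Scnn1a at 1.18 ± 0.20 TPM at its end. The deep-layer list had a median of 12.58 ± 1.00 TPM, led by Pcp4 at 218.81 ± 31.2 TPM, Crym at 42.35 ± 2.35 TPM, Rprm at 33.94 ± 2.21 TPM and Etv1 at 31.27 ± 1.98 TPM, with Foxp2 at 2.82 ± 0.70 TPM and Nxph4 at 2.11 ± 0.44 TPM at its end.

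Astrocyte and myelin genes were the most abundant of the glial lists. The 12 astrocyte genes had a median of 49.52 ± 0.34 TPM, led by the glutamate transporter gene Slc1a2 at 847.69 ± 72.7 TPM, Aldoc at 344.69 ± 11.1 TPM, Slc1a3 at 154.63 ± 12.7 TPM and the gap junction gene Gja1 at 95.86 ± 6.98 TPM; Aldh1l1 at 30.85 ± 3.00 TPM and Sox9 at 10.80 ± 0.71 TPM were the lowest. The 12 mature oligodendrocyte genes had a median of 47.93 ± 8.94 TPM, with the myelin genes Mbp at 405.71 ± 80.9 TPM, Mobp at 114 ± 20.1 TPM and Cnp at 77.75 ± 17.8 TPM. Aspa at 3.45 ± 0.45 TPM and Opalin at 2.80 ± 0.76 TPM ended that list. Oligodendrocyte precursor genes had a median of 8.98 ± 0.75 TPM, with Ptprz1 at 54.18 ± 6.31 TPM, Olig1 at 43.63 ± 5.06 TPM and the growth factor receptor gene Pdgfra at 20.16 ± 0.37 TPM. The 8 genes of differentiating oligodendrocytes had a median of 4.16 ± 1.01 TPM, with Gpr17 at 21.03 ± 1.33 TPM and Enpp6 at 2.64 ± 0.25 TPM. Microglial genes had a median of 15.63 ± 0.16 TPM, with Csf1r at 34.87 ± 0.21 TPM and Trem2 at 3.68 ± 0.20 TPM.

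Vascular and meningeal genes were also present. Endothelial genes had a median of 11.62 ± 1.47 TPM, with the glucose transporter gene Slc2a1 at 50.17 ± 12.2 TPM and the tight junction gene Cldn5 at 27.97 ± 1.94 TPM. Mural genes had a median of 3.50 ± 0.24 TPM, with Vtn at 33.2 ± 0.41 TPM and Kcnj8 at 1.06 ± 0.33 TPM. Fibroblast genes had a median of 11.17 ± 0.72 TPM, with Ptgds, which glial cells also express, at 1070.6 ± 129 TPM and Col1a2 at 14.68 ± 0.47 TPM. Peripheral leukocyte genes were near zero: 0 of 8 were detected, Cd79a had 9 and 6 counts, and Ly6g and Nkg7 had 0 in both libraries, where a count of 0 allows up to 3 counts.

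**Figure D1:**
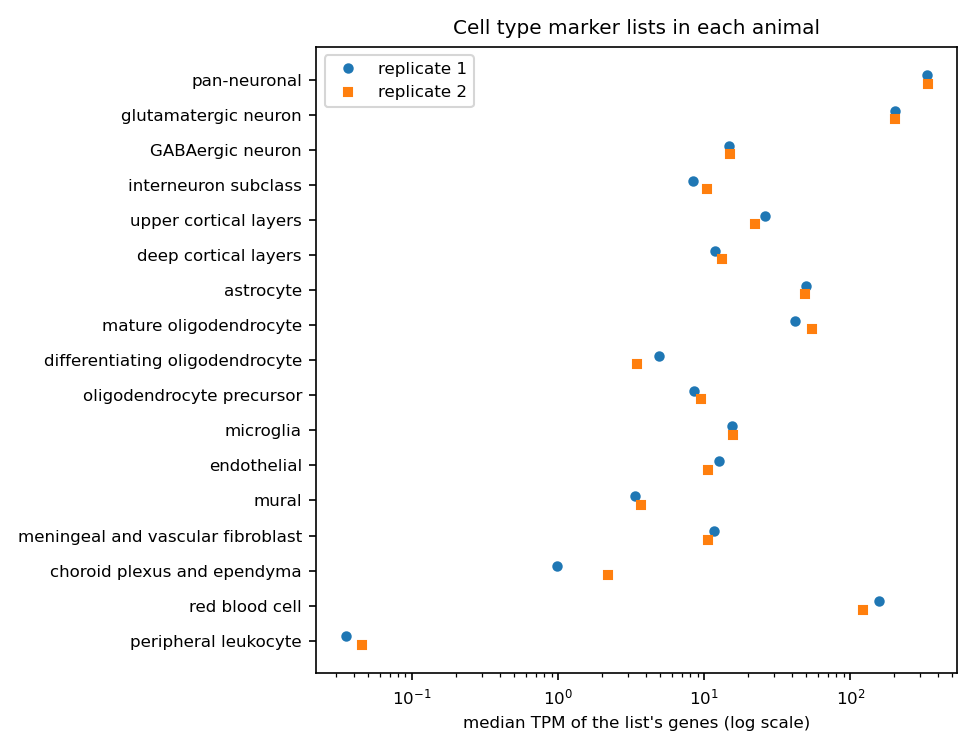
Median TPM of the genes in each of 17 cell type marker lists (horizontal axis, log scale), with a circle for replicate 1 and a square for replicate 2. Pan-neuronal genes lie highest, at a mean of 336.15 TPM, and peripheral leukocyte genes lowest, at 0.04 TPM.

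Markers of neighbouring tissue were mixed. Whether the detected genes of these lists came from cortex itself or from neighbouring tissue in the piece was not tested. In the hippocampal list 6 of 9 genes were detected, such as Ociad2 at 52.65 ± 0.98 TPM and Wfs1 at 50.20 ± 0.63 TPM, while Spink8 stood at 0.82 ± 0.02 TPM and Dsp at 0.15 ± 0.11 TPM. In the striatal list 7 of 10 were detected, led by the signalling gene Ppp1r1b at 61.99 ± 0.28 TPM, with Six3 at 0.35 ± 0.06 TPM and Isl1 at 0.20 ± 0.01 TPM. In the thalamic list 7 of 8 were detected, led by Slc17a6 at 13.26 ± 0.45 TPM, with Gbx2 at 0.07 ± 0.04 TPM. Cerebellar genes had a median of 0.23 ± 0.02 TPM with 3 of 8 detected, Cbln1 at 5.19 ± 1.45 TPM and Gabra6 at 0.02 TPM in each animal. Olfactory bulb genes had a median of 1.08 ± 0.02 TPM with 3 of 6 detected, Cdhr1 at 5.19 ± 0.23 TPM and Eomes at 0.08 ± 0.04 TPM. Haemoglobin genes of red blood cells were abundant, Hbb-bs at 301.08 ± 75.4 TPM and Hba-a1 at 293.05 ± 88.1 TPM, though near-identical paralogs share their reads and each value is uncertain.

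The animals differed in choroid plexus, myelin, immediate early and red blood cell genes, among others. Ttr, which makes transthyretin, the thyroid hormone carrier secreted by the choroid plexus (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), stood at 19.47 TPM in replicate 1 and 191.94 TPM in replicate 2, on 426 and 4698 counts. The log2 difference was 3.27 by TPM, and the 95% counting interval from exact binomial limits on TMM-scaled counts ran from 3.19 to 3.48. All 9 members of the choroid plexus and ependyma list with a mean count of at least 10 were higher in replicate 2, with a median log2 difference of 0.65, at percentile 100 of 10000 random lists matched on expression. Folr1 stood at 0.59 and 2.26 TPM, Clic6 at 0.33 and 1.2 TPM and Aqp1 at 0.24 and 1.09 TPM, all on under 90 counts.

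All 12 mature oligodendrocyte genes were higher in replicate 2, with a median log2 difference of 0.41 (percentile 100). Mbp stood at 348.48 TPM in replicate 1 and 462.93 TPM in replicate 2, Cnp at 65.17 and 90.32 TPM, Mag at 47.69 and 66.53 TPM, Ermn at 4.36 and 6.51 TPM and Opalin at 2.26 and 3.33 TPM. Of the deep-layer genes 13 of 14 were higher in replicate 2 (median log2 difference 0.16, percentile 100). The number was 12 by TMM-scaled counts, where Etv1 turned (-0.013), and 12 in the second file, where Syt6 turned (-0.018). Those higher by TPM included Tle4 at 13.72 and 18.12 TPM and the transcription factor gene Foxp2 at 2.32 and 3.31 TPM. Cplx3 at 5.23 and 7.61 TPM and Syt6 at 3.39 and 4.53 TPM were also among them. Striatal genes had a median log2 difference of 0.14 (percentile 99.55), with Drd1 at 9.03 and 10.42 TPM, Rgs9 at 5.6 and 7 TPM, Drd2 at 0.65 and 1 TPM and Six3 at 0.3 and 0.39 TPM. That list lay at percentile 96.42 in the second transcript file and at 96.95 when every member with any count was taken, a setting chosen after seeing the data. Upper-layer genes were lower in replicate 2 in 10 of 10 cases by TPM (median log2 difference -0.22, percentile 0.01) and in 9 of 10 by TMM-scaled counts, where Otof turned (0.053), and in the second file, where Scnn1a turned (0.25), with Cux2 at 112.17 and 89.54 TPM, Rasgrf2 at 109.64 and 84.05 TPM, Cartpt at 17.48 and 14.17 TPM and Scnn1a at 1.32 and 1.04 TPM.

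All 15 immediate early genes, which neurons transcribe within minutes of activity, were lower in replicate 2, with a median log2 difference of -0.75 (percentile 0). Arc (ENSMUSG00000022602.14, chromosome 15, 74669083 to 74672570) stood at 166.91 TPM in replicate 1 and 82.15 TPM in replicate 2, Nr4a1 at 87.81 and 48.37 TPM, Dusp1 at 28.14 and 14.27 TPM, Npas4 at 12.33 and 5.4 TPM, Egr1 at 139.25 and 99.07 TPM and Junb at 54.26 and 32.03 TPM. Glucocorticoid and stress genes were lower in replicate 2 in 9 of 10 cases (median log2 difference -0.31, percentile 0), or 8 in the second file, with Fkbp5 at 31.25 and 20.26 TPM, Zbtb16 at 48.26 and 32.22 TPM, Hspa1b at 6.75 and 4.33 TPM and Plin4 at 1.07 and 0.6 TPM. Circadian clock genes were lower in 13 of 14 cases, or 12 by TMM-scaled counts or in the second file (median log2 difference -0.26, percentile 0; -0.16 by TMM-scaled counts and -0.12, percentile 1.27, in the second transcript file), with Per1 at 64.54 and 43.2 TPM, Per3 at 12.81 and 8.32 TPM, Per2 at 18.01 and 13.11 TPM and Ciart at 9.38 and 5.66 TPM.

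Other lists also lay outside the range of random lists. Red blood cell genes were lower in replicate 2 in 5 of 5 measured cases (median log2 difference -0.52, percentile 0), with Hba-a1 at 355.35 and 230.74 TPM, Hba-a2 at 271.89 and 208.35 TPM and Alas2 at 5.57 and 3.5 TPM. The list called nuclear or non-polyadenylated RNA had a median of -0.18 (percentile 0), with 9 of 13 members lower, or 8 by TMM-scaled counts and 7 in the second file. Its members included Lars2 at 29.06 and 15.58 TPM, Neat1 at 14.62 and 11.61 TPM and Kcnq1ot1 at 2.84 and 2.17 TPM, but Terc on 7 and 14 counts. The abundant members Rn7sk, at 50715.6 and 54194.4 TPM, and Rn7s1 and Rn7s2, at 141042 and 141598 TPM each, were also higher in replicate 2. Rmrp counted as lower at a log2 difference of -0.0087, but a shorter annotated copy that overlaps it was higher (0.38), so its direction is uncertain. Astrocyte genes had a median of -0.10 (percentile 0.24), with Slc1a2 at 899.12 and 796.26 TPM, Gjb6 at 48.88 and 42.95 TPM and Aldh1l1 at 32.97 and 28.73 TPM, but Gfap at 45.5 and 51.41 TPM; against unmatched random lists that percentile was 10.8. Differentiating oligodendrocyte genes had a median of -0.23 (percentile 0.75), which was -0.09 (percentile 5.03) by TMM-scaled counts and -0.12 (percentile 16.16) in the second file, with Bmp4 at 5.06 and 3.09 TPM, Nkx2-2 at 3.53 and 2.62 TPM and Tcf7l2 at 4.69 and 3.54 TPM, but Bcas1 at 16.16 and 19.95 TPM; Nkx2-2 turned to 0.0041 by TMM-scaled counts and Tcf7l2 to 0.0075 in the second file. The proliferation list, with 0 of 8 genes detected, had a median of 0.34 (percentile 99.24) over 4 genes, with Mki67 on 32 and 65 counts, Top2a on 26 and 50, Ccnb1 on 15 and 17 and Ccna2 on 27 and 28. By TMM-scaled counts and in the second file, at medians of 0.29 and 0.18, that list lay inside the range of random lists, and with a pseudocount of 0.1 its median was 0.66. Interferon response genes had a median of 0.18 (percentile 98.41), or 0.29 in the second file, with Bst2 on 14 and 29 counts and Oasl2 on 10 and 30 counts, but Rtp4 on 23.02 and 16, which the second file gave as higher (0.31). Its percentile was inside the central range with a pseudocount of 0.1.

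In all, 14 of 35 lists lay outside the central range of matched random lists, where 1.75 would by chance if genes were independent. Random lists do not carry the correlation between genes of 1 cell type, so the percentiles are a description of these 2 libraries and not p-values. Scaling to the spike-in total moved the median of all genes to 0.14, and the differences given here are relative to the rest of the genes. Neuron lists lay inside, with signs that varied with the scaling or the file for all but the GABAergic list, at a median log2 difference of -0.02 for pan-neuronal and for glutamatergic genes and 0.01 for GABAergic and for interneuron subclass genes. So did microglia at -0.03, oligodendrocyte precursors at 0.04, endothelial genes at -0.06, mural genes at -0.02, fibroblast genes at -0.08, hippocampus at -0.04, thalamus at -0.17, cerebellum at 0.20 and olfactory bulb at -0.08. By TMM-scaled counts the endothelial (-0.079, percentile 1.95), household (0.053, percentile 98.51) and sex check lists (-0.15, percentile 1.42) lay outside, and against unmatched random lists the cerebellum (percentile 98.83) and MHC class I lists (percentile 97.58) did. Medians turned sign by TMM-scaled counts for cerebellum (-0.084, and 0.033 in the second file), hippocampus (0.0068), microglia (0.003) and mural genes (0.037, and 0.018 in the second file), in the second file for thalamus (0.017, and -0.0063 by TMM-scaled counts), and with all members with any count for olfactory bulb (0.031).

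**Figure D2:**
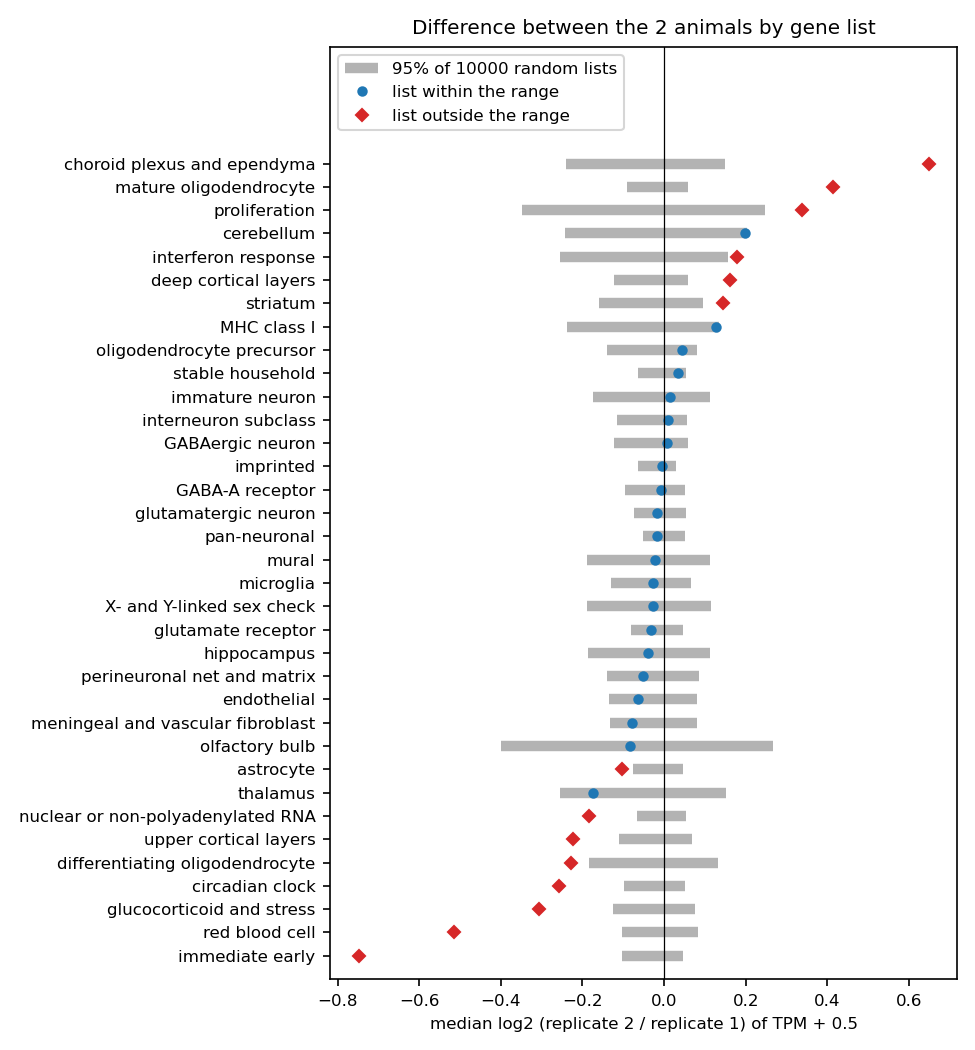
Median log2 difference between replicate 2 and replicate 1 for each of 35 gene lists (horizontal axis, log2 of TPM + 0.5), with grey bars for the central 95% of 10000 random lists matched on expression. Red diamonds mark the 14 lists outside the bars, from immediate early genes at -0.75 to choroid plexus genes at 0.65.

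Across genes the libraries were close. Over 18136 genes with a mean expected count of at least 10, the Pearson correlation of log2(TPM + 0.5) was 0.992 and the Spearman correlation 0.992, both across genes, which are not independent replicates. By TPM 126 genes were over 2-fold apart, 72 higher and 54 lower in replicate 2; by counts scaled to the spike-in total the split was 61 and 30. By counts scaled to library size with no pseudocount, a setting chosen after seeing the data, 470 genes were 2-fold apart or more, where counting error alone would give 170.57. The edgeR common dispersion gave a biological coefficient of variation of 5.61%, which takes in every real difference between the animals. The chi-square of the counts was 5.56 times its degrees of freedom, so the tables are not copies of 1 library.

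The largest single differences were partly of genes with shared reads. After Ttr, the genes highest in replicate 2 were Gm10359, at 2.36 and 11.87 TPM, and Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4, 4 copies of a small nucleolar RNA with the same value, 22.63 and 82.96 TPM, in each. Gm20388, Gm13394, Gm14440 and Rpl10a-ps1 completed the 10, at log2 differences from 1.25 to 1.54. The genes lowest in replicate 2 were Gm14288, on 363.77 and 0 counts, and 1700047I17Rik2, on 238.84 and 14.61 counts, followed by Gm47075, C630044B11Rik, Npas4, AL731706.1, Ccl21b, Fam220a, Gm44597 and the matricellular protein gene Ccn1 at 4.92 and 2.17 TPM. In the second transcript file 3 of the 10 highest and 6 of the 10 lowest were still over 2-fold apart in the same direction. Gm14288 and Gm14440 belong to a family of near-identical zinc finger genes on chromosome 2, and the second file gave Gm14288 at 8.90 and 7.82 TPM.

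**Figure D3:**
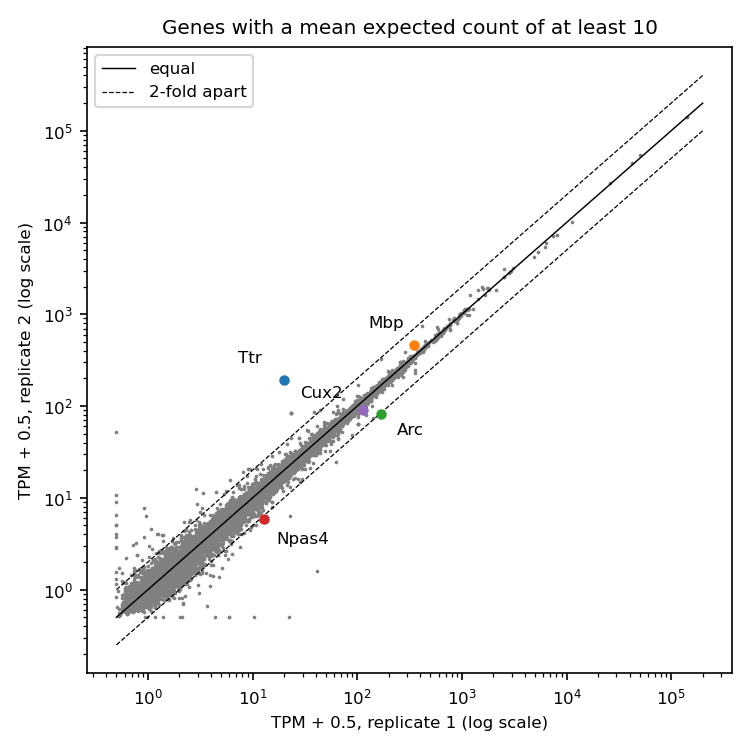
TPM + 0.5 of each gene with a mean expected count of at least 10 in replicate 1 (horizontal axis, log scale) against replicate 2 (vertical axis, log scale), with lines for equal values and for 2-fold differences. Most of the 18136 genes lie between the dashed lines, and Ttr lies far above them at 19.47 and 191.94 TPM.

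Ratios of gene pairs, which do not depend on library scaling, were positive for the first-listed gene in both animals in 15 of 20 pairs. Slc12a5, the neuronal chloride exporter gene, exceeded the chloride importer gene Slc12a2 by 18.3-fold (log2 ratio 4.20 ± 0.04, n = 2), Scn1a exceeded Scn3a by 3.08-fold (1.62 ± 0.06) and Dlg4 exceeded Dlg3 by 6.17-fold (2.63 ± 0.03). Grin2b still exceeded Grin2a by 1.35-fold (log2 of Grin2a over Grin2b -0.43 ± 0.02). Slc17a7 exceeded Slc17a6 by 50.5-fold (5.66 ± 0.07) and Gad1 by 4.90-fold (2.29 ± 0.02), Gad1 exceeded Gad2 by 3.28-fold (1.71 ± 0.02), Syt1 exceeded Syt2 by 29.9-fold (4.90 ± 0.16) and Camk2a exceeded Camk2b by 4.33-fold (2.11 ± 0.13). Sst exceeded Pvalb by 4.56-fold, Slc1a2 exceeded Slc1a3 by 5.48-fold, Gria2 exceeded Gria1 by 2.39-fold and Kcna2 exceeded Kcnc1 by 1.25-fold. The widest spreads between animals were those of Cux2 over Fezf2 (2.96 ± 0.33) and Mbp over Pdgfra (4.32 ± 0.32), with Mbp over Enpp6 at 7.26 ± 0.15. Hba-a1 and Hbb-bs were level (-0.05 ± 0.08).

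Receptor, matrix, developmental, MHC class I and household lists lay inside the range of random lists by TPM. Glutamate receptor genes, 12 of 12 detected, had a median of 90.95 ± 0.02 TPM, with Gria2 at 225.99 ± 5.69 TPM, Grin1 at 198.49 ± 12.1 TPM and Grin2d at 4.68 ± 0.12 TPM (median log2 difference -0.03, or 0.0012 by TMM-scaled counts). GABA-A receptor genes, 11 of 11 detected, had a median of 43.42 ± 1.22 TPM, with Gabrg1 at 7.57 ± 0.45 TPM (-0.01, or 0.028 by TMM-scaled counts). Perineuronal net and matrix genes had a median of 21.56 ± 0.86 TPM, with Bcan at 113.44 ± 1.38 TPM and Acan at 1.42 ± 0.11 TPM (-0.05). Of 8 immature neuron genes 6 were detected, with Tubb2b at 89.34 ± 5.56 TPM, Dcx at 11.02 ± 0.36 TPM and Draxin at 0.12 ± 0.06 TPM (0.02). MHC class I genes had a median of 5.67 ± 0.04 TPM, with B2m at 44.09 ± 4.00 TPM (0.13, percentile 97.06). Household genes had a median of 445.68 ± 6.44 TPM, with Gapdh at 1105.6 ± 33.2 TPM and Tbp at 11.17 ± 0.23 TPM (0.03).

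Genes listed as imprinted, a term for transcription mainly from 1 parental copy, were detected in 30 of 34 cases. Whether each of them is so transcribed in this tissue was not measured. Their median was 34.03 ± 0.12 TPM, with a median log2 difference of -0.005 between animals, or 0.0038 by TMM-scaled counts. Meg3 stood at 1060.8 ± 95.6 TPM, Gnas at 763.23 ± 1.77 TPM and Snhg14 at 727.63 ± 66.3 TPM. Snurf was listed at 1082.2 ± 57.4 TPM, but it overlaps Snrpn and its value is uncertain. Asb4 at 0.39 ± 0.07 TPM and Calcr at 0.07 ± 0.02 TPM were the lowest. The tables sum both alleles, so parental origin was not analysed here.

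Small structural RNAs took much of the TPM scale and little of the counts. The 7SL RNA genes Rn7s1 and Rn7s2, RNA components of the signal recognition particle, each stood at 141320 ± 393 TPM, with identical values in the table for these near-identical copies, and Rn7sk, which regulates transcription elongation, stood at 52455 ± 2460 TPM. The mitochondrial ribosomal RNA genes mt-Rnr2 and mt-Rnr1 followed at 43168.4 ± 1557 and 26363.1 ± 618 TPM, then Gm26917 at 10716.7 ± 677 TPM, the RNase P RNA gene Rpph1 at 7741.81 ± 500 TPM, Gm28661 at 7271.76 ± 184 TPM, mt-Co1 at 6199.28 ± 218 TPM and Gm10925 at 5794.86 ± 577 TPM. Gm28661, Gm10925 and Gm28437 are pseudogenes on chromosome 1 that resemble mitochondrial genes, and their values are uncertain because reads can be shared between the copies. Among nuclear-encoded genes the 10 highest also held Gm28437 at 5089.53 ± 413 TPM, Malat1 at 4542.64 ± 484 TPM and Rmrp at 2894.25 ± 12.3 TPM. A shorter annotated copy of Rmrp overlaps this entry and stood at 1409.8 TPM in replicate 1 and 1841 TPM in replicate 2. The value of each Rmrp entry is therefore uncertain.

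By class, nuclear protein-coding genes held 45.4% ± 0.41 of TPM and 81.1% ± 0.11 of expected counts, and the misc_RNA class, with Rn7s1, Rn7s2 and Rn7sk, held 33.5% ± 0.33 of TPM and 4.61% ± 0.13 of counts. Mitochondrial ribosomal RNA held 6.95% ± 0.22 of TPM, pseudogenes 3.31% ± 0.10, genes annotated as long non-coding or TEC 3.10% ± 0.21, mitochondrial protein-coding genes 2.66% ± 0.10 and snRNA 2.29% ± 0.10. Within the long non-coding and TEC class, Gm26917, annotated as lincRNA, alone held 1.07% of TPM. In the second transcript file protein-coding genes held 75.6% ± 0.02 of TPM and the misc_RNA class 0.003%.

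**Figure D4:**
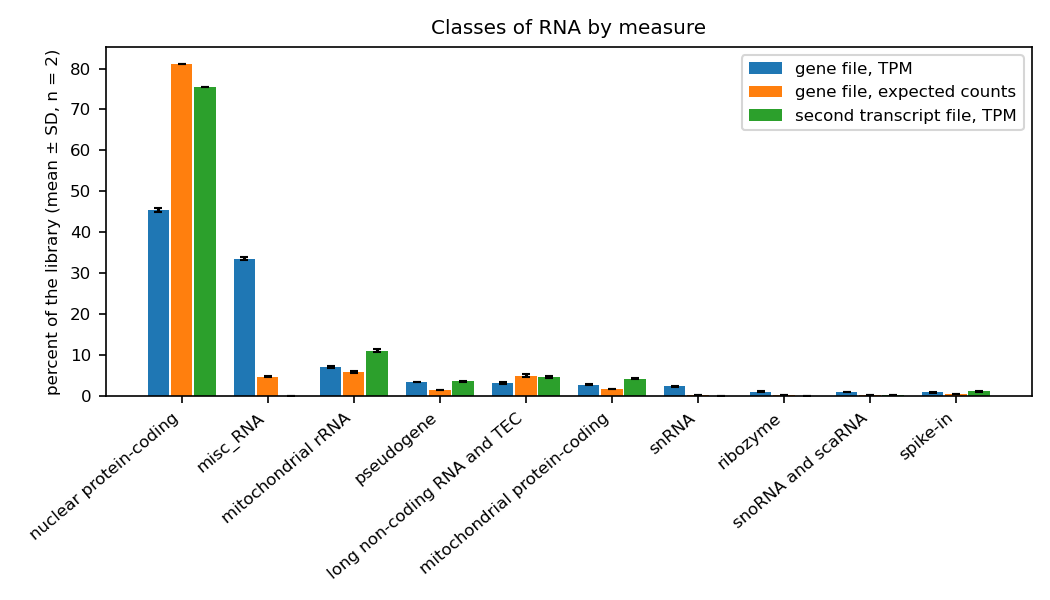
Percent of each library (vertical axis) held by the main classes of RNA, as bars for the mean of 2 animals with SD, by TPM and by expected counts in the gene file and by TPM in the second transcript file. The misc_RNA class holds 33.5% of TPM in the gene file but 4.61% of its counts.

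Y-linked genes matched the male label of both animals. Ddx3y stood at 22.79 and 22.77 TPM, Eif2s3y at 29.07 and 23.45 TPM, Uty at 11.48 and 11.46 TPM and Kdm5d at 8.14 and 6.35 TPM. Xist, which is transcribed from an inactive X chromosome, stood at 0.03 and 0.02 TPM on 10 counts in each library, and Tsix had 0 and 1 counts.

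The second transcript file gave higher TPM for most genes and far lower values for short RNAs. Over genes at 1 TPM or more in either file, the median log2 ratio of the second file to the gene file was 0.63 ± 0.01 (n = 2), the Spearman correlation across genes was 0.899 ± 0.002, and 10.9% ± 0.52 of genes lay over 2-fold from the median. The 154 genes under 300 bases at 5 TPM or more in either file, in both animals, had a median log2 ratio of -6.42, while genes from 1000 to 3000 bases had one of 0.68. Rn7s1, Rn7s2, Rn7sk, Rmrp, Gm23444, Gm23472, mt-Atp8, Gm24265 and Gm24407 were lowest in the second file, at mean log2 ratios from -16.28 to -11.76, and a shorter annotated copy of Rmrp stood at -11.65. Highest in the second file were Gm47283, Gm28439, Gm47673, Gm26905, Gm47408, Gm48765, Gm38356, Gm42860, Gm47164 and Gm47031, from 8.59 down to 6.76, of which Gm47283, Gm28439, Gm47673, Gm47408, Gm38356 and Gm47031 had 0 counts in the gene file in both animals.

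Main isoforms were alike in the animals and less so between the files. For 39 of 40 genes the same transcript had the highest share of TPM in both animals. For 30 of 40 the same transcript led in both files by the mean of the animals. In 21 genes 1 transcript held over 50% of TPM in each animal, against 31 by share of expected counts, which weighs long transcripts more. In the second file 18 genes had a transcript over 50% in each animal. For Cnp it was not the same one there, with Cnp-201 at 51.3% in replicate 1 and Cnp-204 at 54.1% in replicate 2. Snap25-201 held 82.6% ± 0.81 of Snap25, App-201 92.5% ± 0.37 of App, ENSMUST00000109813.8 89.2% ± 2.32 of Camk2b, Kif1b-203 81.3% ± 0.31, Cltb-201 78.4% ± 0.52, Clta-205 75.0% ± 0.75, Mapt-204 73.5% ± 0.87, Gria1-201 67.6% ± 0.45, Gria3-201 65.3% ± 0.12, Rbfox1-201 64.5% ± 0.36, Camk2a-203 63.8% ± 1.25, Cdc42-201 62.1% ± 0.004, Nfasc-202 59.2% ± 0.001, Gria2-202 59.0% ± 1.94, Dlg4-203 57.2% ± 2.26, ENSMUST00000113690.7 55.6% ± 0.61 of Tpm1 and Gnas-208 54.7% ± 0.17.

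In the next genes no transcript held over 50% of TPM in both animals. Pkm-202 held 49.6% ± 0.14 and Pkm-201 47.9% ± 0.60, Mag-203 49.6% ± 2.31, Dnm1-201 47.9% ± 0.29, Ube3a-203 43.4% ± 2.92, Grin1-201 42.8% ± 3.17, Map2-204 42.3% ± 0.59, Ntrk3-202 40.5% ± 0.16, Stx3-203 40.1% ± 9.46, Ntrk2-201 39.2% ± 1.33, Tpm3-202 38.6% ± 1.60, Nrxn3-205 38.3% ± 0.03, ENSMUST00000111050.9 37.0% ± 6.74 of Bdnf, Homer1-207 29.7% ± 1.44, Meg3-203 25.9% ± 1.35, Ank2-201 19.9% ± 0.10 and Ank3-244 19.004% ± 0.21. Homer1 was the gene whose leading transcript differed between the animals. In replicate 1 Homer1-204 at 29.57% exceeded Homer1-207 at 28.64%, and in the second file at 25.63% against 24.64%. By share of expected counts, Ube3a-203 held 83.1%, Mag-203 65.4% and Nrxn3-205 60.7%. By that share Ntrk3-201 at 69.2% led over Ntrk3-202 and ENSMUST00000146701.7 at 78.3% over Meg3-203 at 2.72%. Likewise Homer1-204 at 44.75% led over Homer1-207, Pkm-201 at 53.13% over Pkm-202 and Ank2-207 at 40.99% over Ank2-201. The files disagreed for Snrpn, where Snrpn-201 held 96.3% ± 0.48 in the first file and Snrpn-202 held 99.9% and 100% in the second. Mbp-211 held 65.1% ± 0.19 in the first file and 26.5% and 29.9% in the second, and Cnp-201 64.9% ± 0.69 against 51.3% and 45.8%. By the mean of the 2 animals these 3 transcripts lost the lead there, as did Meg3-203 at 0% in each animal, Stx3-203 at 24.3% and 12.7%, Tpm3-202 at 18.5% and 21.4%, Grin1-201 at 26.73% and 26.98%, ENSMUST00000111050.9 of Bdnf at 14.4% and 41.5%, Ube3a-203 at 36.9% and 35.1% and Pkm-202 at 43.1% and 40.5%. In replicate 2 of the second file Mbp-211 still led over Mbp-201 at 29.4%, and ENSMUST00000111050.9 over Bdnf-201 at 30.0%. In replicate 1 Cnp-201 still led over Cnp-204 at 48.5%. Dlg4-203 at 29.2% and 29.9%, Nfasc-202 at 46.6% and 48.3%, ENSMUST00000113690.7 of Tpm1 at 46.2% and 47.0% and Gnas-208 at 49.2% and 50.1% kept the lead but no longer held over 50% in both animals.

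Of 96 spike-in RNAs, 62 had at least 1 expected count in both libraries. They held 0.43% of the counts in replicate 1 and 0.39% in replicate 2. Over the 40 with at least 10 counts in both, the median log2 difference between replicate 2 and replicate 1 was -0.20, and log2 TPM correlated at 0.997 across spike-ins. The lowest detected mean was 0.04 TPM and the highest 1525.4 TPM.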

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

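The test of a nuclear RNA share was chosen only after the values it measures were seen, the 5 follow-up lists were chosen after the values of the fixed lists were seen, and the test of near-identical transcripts was added after the strand and host gene results and the names of the genes were seen, though before its own value. The numbered features that name no gene held 7 expected counts in replicate 1 and 10 in replicate 2, above the 3 counts that a count of 0 allows; they stood out because no comparison used them, and they form a negligible share of either library.

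Choroid plexus, myelin and deep-layer genes were higher and upper-layer genes lower in replicate 2; the design has 1 group and gives no biological explanation to test for this or the next patterns, and those weighed concern the piece of tissue, the time before collection and the counting of reads. A candidate explanation for the choroid plexus genes is choroid plexus tissue in the piece of replicate 2: a follow-up list of 16 genes had a median of 0.32 (bootstrap interval 0.14 to 0.93), at percentile 100 of matched random lists, with 14 of 14 measured members higher, or 12 in the second file. Of the 16, 7 reached 1 TPM in replicate 1 already, its most abundant gene Enpp2, which other brain cells also express, stood at 117.97 and 133.04 TPM, and the widest ratios rest on few counts, such as Kcne2 with 2 and 26, both genes named after their values were seen. More deep cortex and white matter in that piece may account for the rest, but the test could not decide it. Follow-up deep-layer and upper-layer medians differed by 0.26 (0.01 to 0.32), at percentile 100 of random pairs of lists. Of 16 deep-layer members 10 were higher and 6 lower (14 and 13 higher by TMM-scaled counts and in the second file). Of 16 upper-layer members 13 were lower (11 and 13). For the myelin genes, a follow-up list of mature oligodendrocyte genes had a median of 0.29, at percentile 100 of matched random lists. Of its members 15 of 15 were higher, or 14 in the second file. The fixed differentiating oligodendrocyte list did not rise with them (-0.23, 2 genes higher and 6 lower). Precursor genes were split (0.04, 5 higher and 5 lower). All these follow-up lists mark the same cells as the fixed lists and were chosen after those were seen. Their medians therefore mainly repeat the pattern.

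Immediate early genes were lower in replicate 2, by a median log2 difference of -0.75. A difference in activity or handling before collection may account for this, but the test could not decide it. A follow-up list of 17 activity-dependent genes had a median of -0.39 (-0.56 to -0.11), at percentile 0 of matched random lists, with 14 members lower. Those genes also follow activity and were chosen after the immediate early values were seen. Their low median therefore mainly repeats the pattern. A larger nuclear RNA share in the library of replicate 1 stays open: the immediate early median of -0.75 lay below the bound of -0.34 from random lists of 1424 sense-intronic and TEC genes, but its exact bootstrap interval, -0.85 to -0.33, reached just past that bound, so closely that intervals from simulated draws, tried before, ended on either side of it. Those nuclear genes had themselves a median of -0.19, and the labels used here give no time of collection.

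A set of 166 genes stood at least 8-fold higher in the second transcript file than in the gene file, relative to the median ratio, in both animals. Reads assigned without regard to strand are argued against, as 1.20% of the set overlapped an exon of an expressed gene on the opposite strand, against 12.6% of 11687 other genes. Reads from a same-strand host gene stay open, with an overlap in 17.5% of the set (Wilson interval 12.4 to 24.0) against 4.70% of other genes, a higher share but still a minority of the set. Reads shared with near-identical transcripts are a candidate explanation. Of the set, 66.9% (59.4 to 73.6) had at least 50% of their 31-base words in a transcript of another gene, against 4.40% of 1000 other genes. The other genes of these comparisons were at 5 TPM or more and not matched on biotype. The set held 40 processed pseudogenes, 36 TEC, 31 lincRNA and 30 protein-coding genes, so the contrast may reflect the kinds of gene. Shared reads do not cover genes such as Cdk5rap2, named after its value was seen, with 3.24% of its words shared.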

How the results depend on the processing

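No paired analysis was possible because there is 1 group. The settings that took all list members with any count, and library-scaled counts with no pseudocount, were chosen after seeing the data, and the other settings before; leaving out either replicate changed no count by over 1.5 times. Of the lists outside the random range, 5 lost that place in some setting, with no change of sign among the 14. By TMM-scaled counts these were differentiating oligodendrocyte (-0.092) and proliferation genes (0.29); in the second file differentiating oligodendrocyte (-0.12), proliferation (0.18) and striatal genes (0.10); with a pseudocount of 0.1, interferon genes (0.22); against unmatched lists, astrocyte genes (-0.10); and with all members with any count, striatal genes (0.089), when 13 lists lay outside. Under TMM 3 other lists moved outside and under unmatched lists 2.

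Protein-coding genes went from 45.4% of TPM to 81.1% of expected counts and 75.6% in the second file, and the misc_RNA class from 33.5% to 4.61% and 0.0034%. Genes over 2-fold apart went from 126 to 356 with a pseudocount of 0.1, 82 with 1, 567 with no filter, 26 at 100 counts or more and 470 by library-scaled counts with no pseudocount; the Spearman correlation without a filter was 0.954, and the DESeq2 median gave a coefficient of variation of 11.1%. Regional genes detected went from 45 to 28 at 5 TPM and spike-ins from 62 to 40 at 10 counts, as stricter limits must give. Between the files, the median log2 ratio was 0.643 at 5 TPM and 0.542 with no filter, the correlation 0.860 with no filter, and the genes over 2-fold from the median 6.48% and 9.13%. Except where stated, the cause was not tested. Of the gene levels named, 210 moved by over 1 SD in the second file, 202 of them up, and 24 did not; 128 moved when rescaled to nuclear-encoded genes, 128 of them up. Spreads of 2 animals are themselves poorly known. Depth limits genes under about 10 counts, as in the proliferation and choroid plexus lists.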

Other observations

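Among genes chosen after their values were seen, Atp5a1, which makes a subunit of the mitochondrial ATP synthase, stood at 167.96 TPM in replicate 1 and 323.46 TPM in replicate 2, on 7868 and 16851 counts, and the second transcript file gave 254.1 and 510.7 TPM. Herc3 went the other way, at 139.82 and 73.53 TPM, with 283.29 and 160.02 TPM in the second file. Both are abundant, and the differences in counts, 6718 and 4083 for Herc3, went the same way as those in TPM. Klf4, a transcription factor gene, stood at 5.75 and 2.62 TPM, in the direction of the immediate early genes.

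The imprinted list had a median difference near 0. Of its members, Nnat stood at 100.21 TPM in replicate 1 and 127.79 TPM in replicate 2, while Ndn at 49.88 and 53.12 TPM, Peg3 at 92.08 and 88.02 TPM and Snrpn at 414.38 and 406.91 TPM lay closer together, named here after their values were seen.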
